A study of Mus musculus with 2 samples.

How the data were processed

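Binding of YY1, a zinc finger transcription factor that can activate or repress its target genes, was profiled in mature adipocytes separated by collagenase from the inguinal fat pad (iWAT, a subcutaneous depot) of male wild-type C57 mice. The 2 libraries came from mice kept at room temperature and from mice exposed to cold for 7 days, with 1 library per condition. The labels call the assay ChIP-seq, while the labels' protocols describe CUT&Tag, in which a transposase tethered to the antibody tags the DNA next to the bound protein in native nuclei. Background in such libraries includes tagging of open chromatin.

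Per the submitters' processing notes, BWA, SAMtools, MACS2, deepTools and DESeq2 were used with the mm10 build. Their versions, their settings, the duplicate handling and the control library are not given in the sources used here. The authors deposited 1 peak list per library, so the peaks were called per sample and not on pooled samples. Each listed peak has a score, a fold enrichment at its summit over the local background (a linear ratio), a −log10 p-value, a −log10 q-value and a summit position, all as deposited by the authors. The deposited score equalled the whole part of 10 times the −log10 p in all 1424 entries of both lists. The smallest −log10 p was 5.18 at room temperature and 5.09 after cold. The peak names carry the number 30 in the room temperature list and 4 in the cold list, and what these numbers stand for is not given in the sources used here. The groups follow the labels. If the numbers were housing temperatures in °C, the library labelled room temperature would come from warmer housing, and the baseline of each comparison between conditions would differ from the label.

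The number of fragments covering each summit was recovered from the deposited values, since the lists hold no read counts. With a pseudocount of 1, fold = (pileup + 1) / (background + 1), and p is the Poisson probability of a larger pileup given that background. The whole pileup that satisfied both values was taken. All 165 room temperature entries and all 1259 cold entries were matched within 0.0002 on the −log10 p scale, and the second-best whole number missed by a median of 0.139 at room temperature and 0.398 after cold. One cold entry had a second whole number within this tolerance. On simulated data with the lists' own backgrounds, 165 of 165 and 1259 of 1259 pileups were recovered, which tests the inversion of the formulas and not the formulas themselves. The lowest background in each list was 0.537 fragments at room temperature and 0.57 after cold. The smallest listed widths were 245 bp and 248 bp. Divided by these widths, the lowest backgrounds gave a cold library 1.05 times as deep as the room temperature library. This assumes that the lowest background is the library-wide one and that the smallest width is the fragment length. It also assumes that control scaling and duplicate handling were alike in both libraries. The absolute depths are unknown. Pileups are given with exact 95% Poisson intervals, shares with exact 95% Clopper-Pearson intervals. Both cover counting error only, and fragments can include PCR copies.

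Peaks were counted as listed, with 1 entry per summit. They were called shared where intervals of both lists overlapped by at least 1 bp. Coordinates are mm10 and 1-based. Genes came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with protein-coding and lncRNA genes used. This table gives no strand and no exons, so the planned distance to a transcription start became the distance to the nearer end of a gene, and exons could not be told from introns. For random expectation, each list was placed 1000 times at random on its own chromosomes between the first and last annotated gene. For gene lists, 10000 random lists of the same size were drawn from the 21887 protein-coding genes, matched on gene length deciles but not on expression, and they describe a library without testing the conditions. The same script steps found 200 of 200 planted overlaps and 200 of 200 planted gene ends.

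No p-value was computed between conditions, because 1 library per condition gives no replicate spread. The design, 10 pathway lists, 5 cell type marker lists, part of the alternatives and the rule for named genes were fixed before the data were examined. The comparison of pileups at shared peaks, with its alternatives, and the other alternatives that the closing section names as added were chosen after. Named were the 10 peaks with the highest −log10 q in each list, the 10 strongest shared peaks, the 10 strongest peaks of 1 list only that lie within 1 kb of a gene end, and up to 4 members per gene list, each with the gene it lies in or, outside genes, the nearest gene end. One gene that this rule names is not reported here. The families in the closing section and its tests of depth, of a common factor and of width were chosen after the data were examined. Alternatives covered the peak threshold, the overlap criterion, lists of equal length, the gene end window and the gene assignment. The YY1 motif and repeat content planned for the peaks were not analysed here, since no genome sequence was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.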

Results

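YY1 occupancy was listed at 165 peaks in the room temperature adipocyte library and at 1259 peaks in the cold library, 7.63 times as many. The room temperature entries lay in 162 intervals that together covered 56.7 kb, and the cold entries in 1225 intervals that covered 488 kb. The background floors put the depth of the cold library at 1.05 times that of the room temperature library. The median summit carried 13 fragments at room temperature (quartiles 10 and 17) and 20 fragments after cold (quartiles 15 and 29). The authors' fold enrichment, a value of each peak within its own list, had a median of 7.41 in the room temperature list and 10.5 in the cold list. Of the room temperature peaks, 9 had a q above 0.05, and 0 of the cold peaks did. Each condition had 1 library, so no difference between the conditions has a replicate check. Room temperature is the label's name for the baseline, and the number 30 in that list's peak names leaves open whether the housing was warmer.

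The first comparison asked where YY1 was bound in adipocytes of both conditions. The strongest room temperature peak lay in Septin7, which encodes a cytoskeletal GTPase, 188 bp from the gene's end (chromosome 9, 25251898 to 25252407). Its summit carried 35 fragments at room temperature (95% interval 24.4 to 48.7) and 108 after cold (88.6 to 130). The next was inside Nr3c1, the glucocorticoid receptor gene, 27625 bp from the nearer gene end (chromosome 18, 39491614 to 39492032), with 28 fragments (18.6 to 40.5) against 141 after cold (119 to 166). The strongest cold peak lay 71 bp outside Tpgs1, which encodes a subunit of a tubulin-modifying complex, and within 1 kb of Madcam1 (chromosome 10, 79668914 to 79669853). It carried 135 fragments (113 to 160), against 31 at room temperature (21.1 to 44). A peak in Crat, the carnitine acetyltransferase gene, which also lay within 1 kb of an end of the phosphatase regulator gene Ptpa, carried 33 fragments at room temperature (22.7 to 46.3) and 71 after cold (55.5 to 89.6). The other 6 of the 10 strongest room temperature peaks lay at Morf4l1, Cdk5rap2, Cradd, Eif4g2, Napepld and 0610009B22Rik. Their pileups were 26, 24, 23, 22, 21 and 26 fragments in this order at room temperature, and 86, 112, 96, 86, 99 and 75 after cold. All 10 were in both lists.

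Of the 165 room temperature peaks, 155 overlapped a cold peak (93.9%, 95% interval 89.1 to 97.1). Random placement of the cold list gave a mean of 0.066 overlapped peaks and at most 2. The placements were not held to gene ends, where most peaks of both lists lay, so any 2 lists with that preference would exceed them. At the level of genes, 167 of the 169 protein-coding genes with a room temperature summit within 1 kb of a gene end also had one after cold, where 1234 genes did. Independent lists of these lengths would share 9.53 genes, if drawn from all protein-coding genes without regard to expression. In the other direction, 164 of the 1259 cold peaks overlapped a room temperature peak (13%, 11.2 to 15). With both lists held to the same length, by keeping only the 165 strongest cold peaks, 93 of the 165 room temperature peaks (56.4%) had a cold counterpart.

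The shared peaks were mostly the strong ones of the cold list. Shared cold peaks had a median of 42 fragments and cold peaks without a room temperature counterpart a median of 19. A shared peak had the higher −log10 q in 83.4% of all pairs of a shared and an unshared cold peak. Of the 126 strongest cold peaks 77 were listed at room temperature (61.1%, 52 to 69.7), of the next 126 peaks 25 (19.8%, 13.3 to 27.9), and of the 629 weakest peaks 19.

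**Figure D1:**
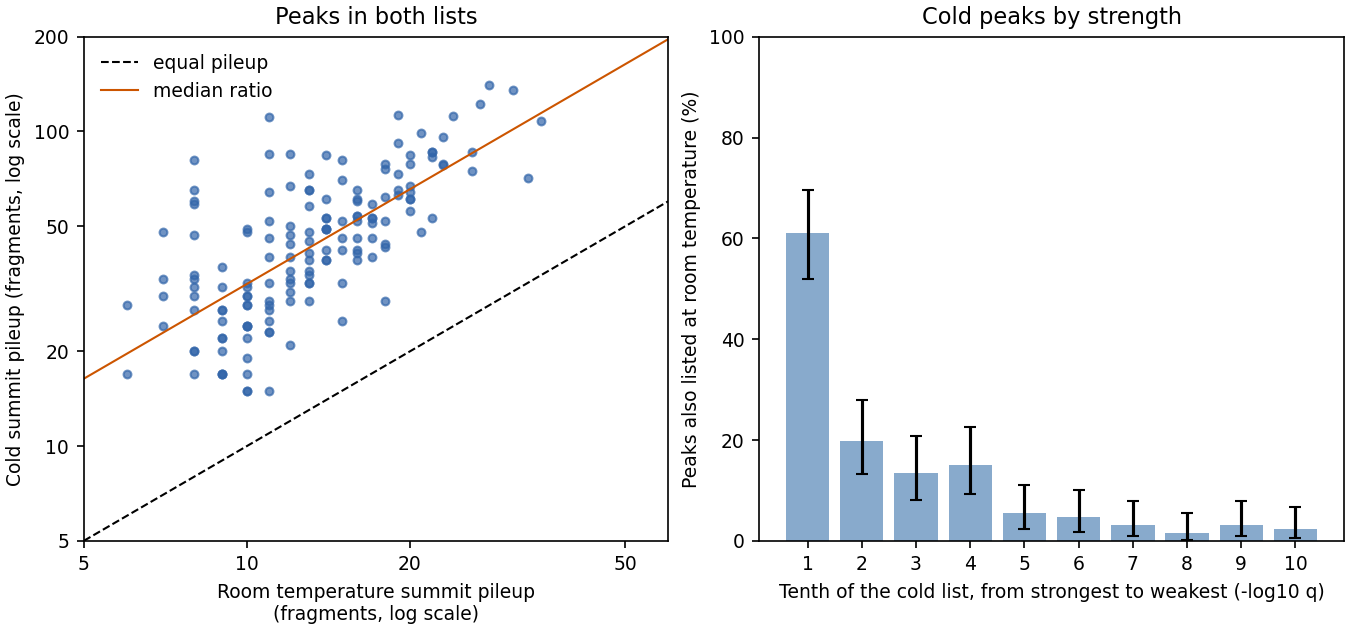
Left, summit pileup (fragments, log axes) of the 154 peaks in both lists with a background of at most 10, 1 point per peak, room temperature on the x axis and cold on the y axis. Right, share of cold peaks also listed at room temperature for 10 equal parts of the cold list by strength, with exact 95% intervals. All points lie above the line of equal pileup, and the share is 61.1% in the strongest part and 2.38% in the weakest.

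The second comparison set the occupancy after cold exposure against that at room temperature. At the 154 shared peaks with a background of at most 10 fragments, the cold pileup was higher at all 154, by a median of 3.28-fold (quartiles 2.57 and 4.17). Scaled by the depth ratio, the median was 3.13-fold (2.45 and 3.98). Across peaks, which are not independent replicates, the pileups of both libraries were correlated (Pearson's r of log2 pileup 0.69, Spearman's rho 0.69). The remaining shared interval (chromosome 2, 98666688 to 98667188 at room temperature) stood on backgrounds of 138 and 150 fragments, and its pileup rose by less, from 209 to 260 fragments, a ratio of 1.24. Its fold enrichments of 1.51 and 1.73 were the lowest of each list. Repeat content was not analysed, so an artifact of read mapping is possible there, and the interval stays in the overlap counts. Shared peaks had to pass the listing threshold in the weaker library, which at a given cold pileup tends to leave out the higher ratios. The median therefore describes shared peaks only, and the ratio of the peaks missing there is not known.

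Among the 10 strongest shared peaks of the cold list, the cold to room temperature ratio was highest at Oxsr1, a stress-responsive kinase gene, at 10.1, with 11 fragments at room temperature (5.49 to 19.7) and 111 after cold (91.3 to 134). The pileups were 19 (11.4 to 29.7) against 113 (93.1 to 136) at Slmap, 15 (8.4 to 24.7) against 81 (64.3 to 101) at Akt1s1, a subunit gene of the growth-regulating mTOR complex, and 27 (17.8 to 39.3) against 122 (101 to 146) at Psmb5, a catalytic subunit gene of the proteasome. At Ywhae, a 14-3-3 adaptor gene, they were 22 (13.8 to 33.3) against 86 (68.8 to 106). The cold summit at Akt1s1 also lay within 1 kb of an end of Tbc1d17. The other 5 peaks lay at Tpgs1, Cdk5rap2, Septin7, Nr3c1 and Cradd, with ratios of 4.35, 4.67, 3.09, 5.04 and 4.17.

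Strong cold peaks without a room temperature entry were found at Txndc15 with 92 fragments (74.2 to 113), Usp31 with 83 (66.1 to 103), the RNA exosome gene Exosc2 with 75 (59 to 94) and Ech1, which encodes an enzyme of fatty acid oxidation, with 73 (57.2 to 91.8). The other 6 of the 10 strongest cold-only peaks at gene ends were those of Zfp672 with Sh3bp5l (82 fragments), Ccdc151 with the glucosidase subunit gene Prkcsh (71), Sdf4 with B3galt6 (71), Szrd1 (67), the inner nuclear membrane protein gene Lemd2 (76) and the ribosome biogenesis gene Wdr75 (68). A missing entry is not a measured 0: the lowest listed pileup at room temperature was 6 fragments, and a site below the listing threshold has no value. The 10 room temperature peaks without a cold overlap were weak, with a median pileup of 6.5 fragments. Of these, 4 had a gene end within 1 kb, and 3 of the 4 lay near the end of the gene that held them, Mettl2 (8 fragments), the RNA helicase gene Ddx3x (6) and the endosomal GTPase gene Rab5a (6). The remaining one, with 8 fragments, lay inside the lncRNA gene Gm36684, 12076 bp from that gene's own nearer end.

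The position of the peaks relative to genes was alike in both libraries. At room temperature 139 of 165 summits lay within 1 kb of a gene end (84.2%, 77.8 to 89.4), and after cold 1062 of 1259 did (84.4%, 82.2 to 86.3). Random placement gave means of 5.09% and 5.05%. A further 11.5% and 12.5% lay inside genes at a greater distance from their ends, against 44.3% and 44.4% of random positions, and 4.24% and 3.18% lay outside genes. Only the outer ends of each gene were known, so a summit at a transcription start inside a gene, as could be at Nr3c1, counts as distant. The median distance to the nearest gene end was 193 bp at room temperature and 162 bp after cold. Of the summits at gene ends, 94 of 139 room temperature summits (67.6%, 59.2 to 75.3) and 782 of 1062 cold summits (73.6%, 70.9 to 76.3) lay on the inner side of that gene. The gene table gives no strand, so these ends can be starts or ends of transcription. Tagging of open chromatin at gene ends was not told apart from YY1 binding there.

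**Figure D2:**
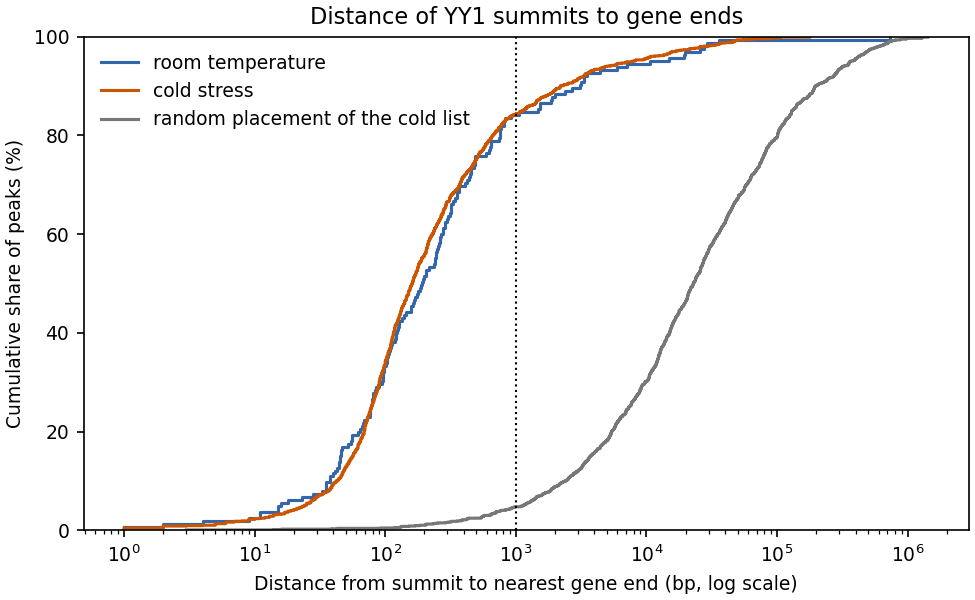
Cumulative share of summits (y axis, %) by distance to the nearest end of a protein-coding or lncRNA gene (x axis, bp, log scale) for the room temperature list, the cold list and 1 random placement of the cold list, with a dotted line at 1 kb. The curves of both libraries run together and reach 84.2% and 84.4% at 1 kb.

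The third comparison asked which gene groups carried YY1, with a summit within 1 kb of a gene end or inside the gene. After cold, 11 of 27 oxidative phosphorylation subunit genes had a peak (40.7%, 22.4 to 61.2), against a mean of 1.8 in random lists, and at most 8. The strongest was the peak at Ndufb5, a complex I subunit gene, shared with an end of the mitochondrial ribosomal protein gene Mrpl47 (chromosome 3, 32736414 to 32737260), with 84 fragments (67 to 104) after cold and 20 (12.2 to 30.9) at room temperature. Next were Sdhb of complex II with 34 fragments, Ndufa9 of complex I with 32 and Atp5o of the ATP synthase with 27, all in the cold list only. Of the 81 cytosolic ribosomal protein genes 20 had a cold peak (24.7%, 15.8 to 35.5), against a random mean of 4.02 and at most 13. Among them were Rpl13a with 59 fragments, Rpl35a, within 1 kb of an end of Iqcg, with 32 and Rpl18 with 29. Of 20 genes of mitochondrial gene expression 5 had a cold peak (25%, 8.66 to 49.1), a number that 1.18% of random lists reached, among them Mrps18a with 42 fragments, Mrps12 with 31, Mrpl9 with 20 and Mrps5 with 17. With each peak counted only for its nearest gene end, this list had 3 members with a peak. The summits at Mrps12 and Mrps5 also lay within 1 kb of ends of Sars2 and Zfp661. At room temperature these 3 lists had 1 (Ndufb5, and 0 by the nearest gene end), 0 and 0 members with a peak, where the random means were 0.275, 0.503 and 0.193. The random lists were matched on gene length and not on expression. Tagging of open chromatin, part of the background in such libraries, was not told apart from YY1 binding, since the YY1 motif was not analysed.

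Genes of polyamine metabolism, the pathway that makes spermidine and is named in the study's title, had 3 peaks among 25 members after cold (12%, 2.55 to 31.2) and 0 at room temperature. The random mean was 1.69, and 23.5% of random lists reached 3. The peaks lay in Oaz1, which encodes the antizyme that restrains polyamine synthesis, with 31 fragments (21.1 to 44; chromosome 10, 80826552 to 80826973), and in both enzyme genes of hypusine synthesis, a protein modification made from spermidine. These were Dhps with 27 fragments (17.8 to 39.3; chromosome 8, 85071498 to 85071828) and Dohh with 23 fragments (14.6 to 34.5; chromosome 10, 81384304 to 81384853). All 3 summits lay inside the gene, 67, 165 and 51 bp from its nearer end. The ornithine decarboxylase gene Odc1, the spermidine synthase gene Srm and the catabolic genes Sat1 and Smox had no listed peak in either library.

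No listed peak lay at any of the 25 thermogenic genes in either library. This list held Ucp1, the uncoupling protein of brown and beige fat, as well as Ppargc1a, Dio2, Cidea and Prdm16. Random lists of this size had a mean of 1.61 members with a peak after cold and 0.212 at room temperature. The interval for 0 of 25 reached 13.7%, above the 6.42% of all protein-coding genes with a cold peak, so the count shows no avoidance. When every peak was given to its nearest gene end instead, 2 thermogenic genes were reached after cold, Ppara from 34.8 kb and 50.6 kb and Ppargc1a from 220 kb. Of 25 genes of adipocyte identity and lipid storage, 1 had a peak, in both libraries. It was Bscl2, which encodes the lipid droplet protein seipin, with 16 fragments at room temperature (9.15 to 26) and 39 after cold (27.7 to 53.3), beside an end of Gng3. For the adipocyte list the random mean was 0.23 at room temperature and 1.68 after cold. The adipocyte genes Pparg, Adipoq and Fabp4 had no listed peak.

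Among 20 genes of YY1 itself and its chromatin partners, 2 had a peak at room temperature and 4 after cold, with random means of 0.201 and 1.53. The room temperature count was reached by 1.81% of random lists and the cold count by 5.81%. With gene ends only, the cold count was 3. Actr8, a subunit gene of the INO80 remodelling complex, had 16 fragments at room temperature (9.15 to 26) and 42 after cold (30.3 to 56.8). The host cell factor gene Hcfc1 was in both lists, with 49 fragments at its strongest cold summit (36.3 to 64.8). Yy1 itself carried a cold peak inside the gene, 1212 bp from its nearer end (chromosome 12, 108793957 to 108794315), with 38 fragments (26.9 to 52.2), and the acetyltransferase gene Ep300 one with 31 fragments (21.1 to 44). The cholesterol and glycolysis list had 1 member of 20 with a peak, Gapdh, after cold (random mean 1.51). The 20 inflammation genes and the 7 protein-coding imprinted or silenced genes measured had 0 in both libraries. Their random means after cold were 1.25 and 0.397, and their intervals reached 16.8% and 41%, so these counts show no avoidance. Of the 5 marker lists, with 8 genes each, those of macrophages, preadipocytes or fibroblasts, lymphocytes and mammary epithelium had 0 members with a peak in both libraries, and the endothelial list had 1, Pecam1, after cold, with 18 fragments (10.7 to 28.4). After cold the random means of the 5 marker lists were 0.496 to 0.596, so counts of 0 or 1 do not set these lists apart. Binding at a marker gene does not measure its expression. The comparison of list counts between conditions follows the longer cold list and was not tested.

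**Figure D3:**
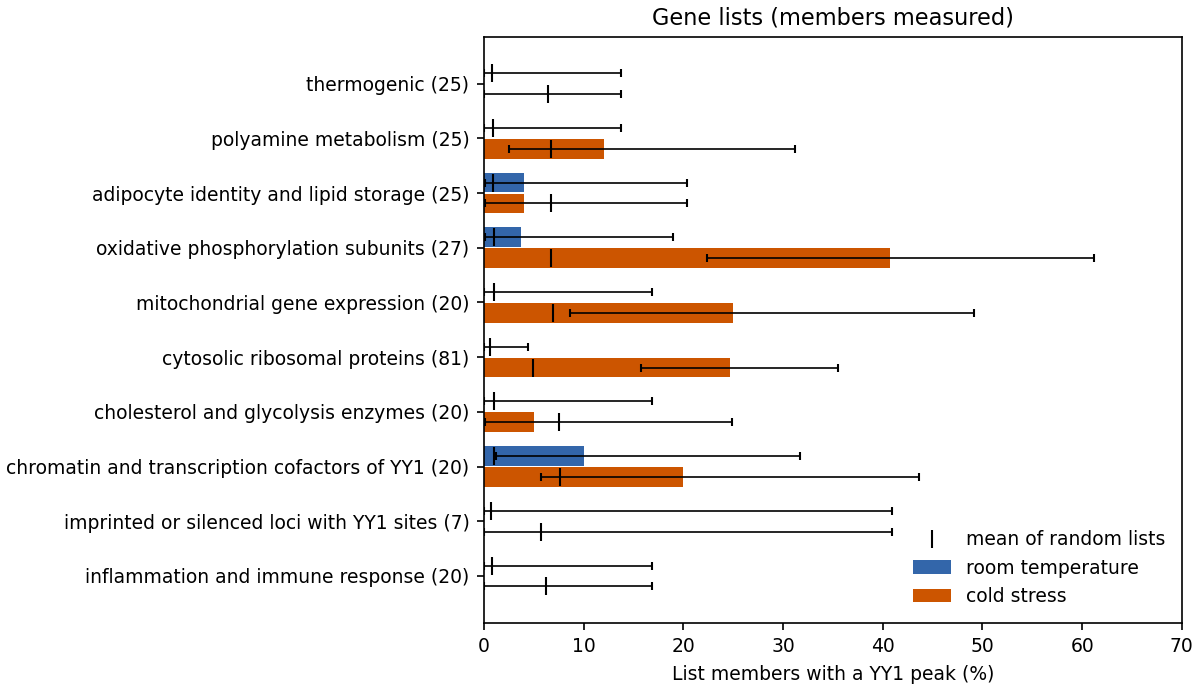
Share of the members of each pathway list with a YY1 peak (x axis, %) at room temperature and after cold, with exact 95% intervals as error bars, the number of members measured in parentheses and black ticks at the mean of 10000 random lists. Oxidative phosphorylation subunits reach 40.7% and cytosolic ribosomal proteins 24.7% after cold. Thermogenic genes stay at 0 in both libraries, with intervals up to 13.7%.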

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

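The settings chosen after seeing the data were distinct intervals, protein-coding gene ends only, leaving out clusters and high background, the other measures of peak strength and the pileup ratio at shared peaks with its alternatives. With 1 library per condition, the depth and the missing replicates limit every comparison, and no library could be left out. No paired analysis was possible because each condition has 1 library. Of the results that answer a comparison, 34 values under an alternative stayed within their interval, quartiles or 1.5 times the reported count, and 13 moved outside, with the cause not tested beyond the settings themselves. Of the counts of single gene lists, 86 stayed and 4 moved, to 0 for oxidative phosphorylation at room temperature, 2 for thermogenic genes after cold and 3 for mitochondrial gene expression after cold with each peak counted for its nearest gene end, and to 0 for cholesterol and glycolysis after cold with gene ends only. The number of peaks stayed within 1.5 times under every alternative run, at 137 to 162 entries at room temperature and 1214 to 1225 after cold. The share of room temperature peaks also listed after cold (93.9%) moved to 78.2% with a reciprocal overlap of 50%, to 98.5% with a −log10 q of at least 3 in both lists, and to 56.4% against only the 165 strongest cold peaks. The share of cold peaks also listed at room temperature (13%) moved to 10.6% and 55.2% under the first and the last of these settings. The share at a gene end moved with the window, to 75.8% (room temperature) and 75.2% (cold) within 500 bp and to 89.7% and 91.5% within 3 kb, and after cold to 80.8% with protein-coding genes only and 88.5% for the strongest 165 peaks. The share of intervals with another within 10 kb was 4.94% at room temperature and 6.53% after cold. In 200 random placements the mean was 0.13% and 1.12%, so this share rises with the length of the list. Within 100 kb the shares were 13% and 31.8%. The median pileup ratio of 3.28 lay between 2.61 and 3.35 under its alternatives, the lowest from the authors' fold enrichment. Gene list totals stayed within 1.5 times, at 3 to 4 members at room temperature and 42 to 45 after cold. The alternatives that need the genome sequence (motifs and repeat masking) were not run.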

Other observations

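The gene families and the tests of depth, of enrichment, of a common factor with its 4 thresholds and of width were chosen after the results were seen, while the tests of background and of gene density were set before. Of 78 mitochondrial ribosomal protein genes 31 had a cold peak (39.7%, 28.8 to 51.5), against a random mean of 4.89 and at most 14 in 10000 lists matched on gene length. Mrps7, Mrpl11 and Mrpl37 carried 31 fragments each. Of 49 genes named as complex I subunits or assembly factors 17 had one (34.7%, 21.7 to 49.6; random mean 3.15, at most 12), with Ndufa13 at 49 fragments, Ndufb1 at 46 and Ndufa2 at 41. Splicing genes had 10 of 32 (31.3%, 16.1 to 50; random mean 2.15, at most 9), with Srsf3 at 53 fragments and Sf3b3 at 33, and proteasome genes 11 of 51 (21.6%, 11.3 to 35.3; random mean 3.44, at most 14, with 0.05% of lists reaching 11), with Psmb5 at 122 and Psmd7 at 34. Translation initiation factor genes had 12 of 56 (21.4%, 11.6 to 34.4; random mean 4.11, at most 13, with 0.09% of lists reaching 12), with Eif4g2 at 86 fragments and Eif3e at 37. Of all 21887 protein-coding genes, 6.42% had a cold peak and 0.864% a room temperature peak. At room temperature, complex I genes had 3 of 49 members with a peak (random mean 0.458, reached by 1.18% of random lists), proteasome genes 3 of 51 (0.481, 1.32%) and splicing genes 2 of 32 (0.32, 3.76%). Mitochondrial ribosomal protein genes had 2 of 78 there (0.717, 16%) and translation initiation factor genes 1 of 56 (0.58, 44.1%).

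Solute carrier genes had 10 of 375 members with a cold peak (2.67%, 1.29 to 4.85), against a random mean of 28. Olfactory receptor genes had 0 of 1106, against a random mean of 18.3, and keratin genes 0 of 49. Zinc finger genes of the Zfp series had 37 of 367 (10.1%, 7.2 to 13.6), against a random mean of 27.1, and 3.29% of random lists reached 37. The other 2 families looked at had 6 of 47 members (ubiquitin-specific proteases) and 3 of 28 (RNA polymerase subunits), numbers that 14.8% and 30.7% of random lists reached. Since the random lists were not matched on expression, the family shares cannot tell YY1 binding from tagging of open chromatin at expressed genes. Peaks within 1 kb of a tRNA gene numbered 1 of 165 at room temperature and 10 of 1259 after cold.

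The cold list was 7.63 times as long as the room temperature list, and at shared peaks its pileups were a median of 3.28-fold higher. Sequencing depth is argued against by the background floors, which put the cold library at only 1.05 times the depth of the room temperature library. This holds only if the floors track depth alike in both libraries, as the control and the settings are not given. A more efficient antibody or tagging reaction in the cold library and more YY1 on chromatin after cold exposure are both candidate explanations of the depth-adjusted median of 3.13-fold. They cannot be told apart, because each condition has 1 library. The high-background interval on chromosome 2, with its ratio of 1.24, was also looked at as a check on local background, and as a single interval it decides nothing.

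Of the strongest 126 cold peaks 49 were not listed at room temperature, among them those of Txndc15 and Usp31. Whether counting noise around a single enrichment factor accounts for this cannot be told: at least 8, 10, 13 and 16 room temperature fragments were listed at 76, 73, 61 and 46 peaks, where one factor gave 120, 109, 84.7 and 53.2. In SD of counting noise these differences were -18.5, -10.5, -5.36 and -1.65. At 8, 10 and 13 fragments they passed the limit written as speaking against noise. This comparison, like its 2 earlier forms with simulated ranges of 68 to 88 and 123 to 126 listed peaks for the 77 seen, decides nothing, because the 49 unlisted sites have no measured pileup and 1 library per condition was set against counting noise alone. The first of these forms used a factor matched to the number of shared peaks (10.1-fold), so its range around 77 is partly built in. The second used the median shared pair (3.35-fold). Whether a minimum width of listed peaks contributes cannot be told, since only cold widths could be compared. Unlisted sites have no room temperature width. Within bins of cold pileup, the peak listed at room temperature had the wider cold interval in 69.8% of pairs. That share lay above the central 95% of 10000 permutations (38.9 to 61.2), the side written as speaking for a minimum width, but below their highest value of 71.9. The median cold widths were 567 bp at listed and 472 bp at unlisted sites. The median cold background was 0.74 fragments at unlisted and 0.822 at listed sites, which is the side set beforehand as speaking against higher background, but the difference of -0.0822 lay inside the permuted range of -0.0987 to 0.115, a spread added after the medians were seen, so this stays open together with binding that differs between sites.

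Many summits lay near 2 genes at the same time, as at Ndufb5 with Mrpl47 or Crat with Ptpa. Of the 1017 cold summits within 1 kb of a protein-coding gene end, 261 had ends of at least 2 such genes in reach (25.7%, 23 to 28.5), and at room temperature 42 of 133 did (31.6%, 23.8 to 40.2). Gene density as the whole reason is argued against, since drawn gene ends with as many other gene ends within 100 kb gave a mean of 16.1% and at most 19.1% in 1000 draws for the cold list, and 16.9% and at most 28.6% for the room temperature list. Drawn ends mix starts and ends of genes, because the gene table has no strand, so a preference for promoters in general stays open. Binding at promoters shared by divergent genes is a hypothesis that was not tested apart from it.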
